A study of Mus musculus with 8 samples.

How the data were processed

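The series holds 8 RNA-seq libraries of mouse brain, 2 for each combination of region (hippocampus, frontal cortex) and genotype (MeCP2 knockout, wild type). Per the labels' protocols, tissue was snap-frozen, RNA was extracted with Trizol and purified on RNeasy columns, and 2 ug of RNA per library went into Illumina's TruSeq RNA preparation, version 2 of its guide. The series design says that the RNA came from pools of mice. Per the submitters' processing notes, TopHat 1.4.1, bedtools and the mouse build mm9 were used, with no role or order given. The counting options, the read filters and any use of strand are not given in the sources used here.

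The authors deposited 1 table of raw read counts per region, with no header. Each row gives the chromosome, start, end, identifier and strand of a transcript, followed by 4 count columns. The columns were assigned to libraries in the order in which each sample's description label lists them (KO1, KO2, wt1, wt2), and 0 value columns were left unused. Both tables list the same 55419 rows in the same order. The deposited counts were checked for what they cover. All 6414 spans that are listed more than once carry equal counts in every library. Among 41233 pairs of nested spans on the same strand, the inner span had the higher count in 50, and among 3202 nested pairs on opposite strands in 0. Apart from these 50 pairs, which were not explained, the checked counts behaved as totals over whole genomic spans, introns included, taken without regard to strand. Reads of overlapping loci were therefore not told apart.

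Gene names were not used. The files do not pair the identifiers with names, 0 of the 55419 identifiers occurred in the reference tables of gene names, and the annotation in the reference is of another build. Gene lists for pathways and cell types were part of the design and could not be run without names. A match by span length to the other build was considered and not used. Transcript spans that overlap on the same strand were merged into 26930 loci, and the transcript with the highest total count stands for its locus. The fixed rule for genes with several transcripts was applied in this way to loci. In all, 4641 loci overlap a locus on the other strand.

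Counts were tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest with package defaults, TMM normalization, filterByExpr by group with a minimum count of 10). The filter kept 18120 loci. The 8 libraries entered 1 fit of the 4 group means, with contrasts for the genotype effect in each region, for its difference between regions and for the region difference in wild type. The effect common to both regions came from an additive fit of region and genotype. Calls had a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was computed as its size divided by the square root of the F statistic. CPM values are TMM-normalized, and 0.5 was added to CPM before taking log2 in scores per library. Long loci were those with a span over 100 kb, tested with camera in limma 3.58.1 at a preset correlation of 0.01. Fisher's exact test was used for counts of calls. Folds against a group with 0 counts were computed against a floor of 3 counts over the group, and intervals are at 95%.

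The loci named were to be MeCP2, then per comparison the 10 largest rises and 10 largest falls (8 each way for the regions) among called loci whose groups did not overlap in log2 CPM and whose mean was at least 1 CPM, the 10 with the smallest p where fewer than 5 passed, and the 6 with the smallest p for the difference between regions. Because no names were available by the routes used here, at most 2 identifiers in each direction are printed per comparison, plus the X-linked locus that was chosen after its values were seen as a check of the labels. Of the 375 frontal cortex calls, 365 met the rule, whose mean CPM was taken over all 8 libraries. The hippocampal libraries are called by their labels throughout.

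The scripts were run on simulated data, with counts drawn from the real means, library sizes and dispersions and 200 changed loci. For the frontal cortex comparison on 17950 loci, 53.5% of the loci changed 1.5-fold, 85.5% of those changed 2-fold and 98.5% of those changed 4-fold were called, with 9 unchanged loci called. For the hippocampal comparison on 17946 loci, 55.2%, 84.1% and 100% of these fold sizes were called, with 18 unchanged loci called. For the effect over both regions on 17960 loci the shares were 75.5%, 97.1% and 100%, with 6 unchanged loci called, and for the difference between regions on 17936 loci 17.5%, 65.2% and 92.6%, with 14 unchanged loci called. For the region comparison on 17856 loci they were 70%, 83.9% and 98.5%, with 13 unchanged loci called. DESeq2 called 24 unchanged loci in the frontal cortex comparison. A simulated shift of 0.1 in 2349 long loci of 17924 was recovered as 0.098 with a camera p of 1.18e-12. With no shift, camera made no call. The simulated loci were drawn independently of each other, so this cannot show how the preset correlation performs where loci are correlated.

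Alternatives fixed before the data were examined were other normalizations (DESeq2 size factors, upper quartile), no filter and a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, robust empirical Bayes, a looser threshold of 0.1, each region or genotype fitted alone, a replicate block, each library left out in turn, other cuts on span (50 and 200 kb) and an estimated correlation. Others were added after the data were seen: every distinct span, without loci that overlap the other strand, the regions averaged over both genotypes, the regions with region as the only term, and the frontal cortex long loci in the 4 libraries of the region, with the preset and the estimated correlation.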

Results

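RNA was sequenced from the hippocampus and the frontal cortex of MeCP2 knockout mice, a model of Rett syndrome, and of wild-type mice. MeCP2 is a protein that binds methylated DNA, and its gene lies on the X chromosome. Each of the 4 groups held 2 libraries, made from pooled RNA, so that 8 libraries were compared. The labels do not say whether the libraries of a group came from separate pools, and p-values therefore measure at most the spread between these libraries. Fisher's exact tests treat loci as independent, which loci of the same libraries are not, so their p-values do not measure that spread. The merged loci held between 54500111 counts (frontal cortex wild type 1) and 70221480 counts (the library labelled hippocampus wild type 1). Between 19586 and 19747 of the 26930 loci had at least 1 count in a given library, and 18120 loci were tested. The deposited tables give transcript identifiers with mm9 positions and no gene names, so loci are described by position, span and region. The tests of region preference, the Fisher tests on spans and the comparison of libraries by chi-square were chosen after the data were seen.

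The check of the knockout came first. MeCP2 could not be looked up by name. The X-linked locus with the largest fall in the frontal cortex knockout, among those with a mean of at least 1 CPM, was examined in its place. That choice was made after the values were seen. This locus, uc009tnt.1, spans 58.8 kb on the minus strand of chromosome X (71272161 to 71330975, introns included). In frontal cortex it stood at 115 ± 5.6 CPM (SD, n = 2) in wild type and 16.7 ± 2.0 CPM (SD, n = 2) in the knockout. Its log2 fold change of -2.79 was the 3rd largest fall among the 15200 loci with a mean of at least 1 CPM. In hippocampus the levels went against the labels. The library labelled wild type 1 held 144 CPM and that labelled wild type 2 held 11.6 CPM, whereas the library labelled knockout 1 held 10.7 CPM and that labelled knockout 2 held 149.8 CPM. Because the fit pools the spread of all groups, the standard error of the frontal cortex change was 1.21 and its adjusted p was 0.226 (edgeR quasi-likelihood test, Benjamini-Hochberg). With the frontal cortex libraries fitted alone, the standard error was 0.10 and the adjusted p was 0.000103.

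A neighbouring locus 2900 bp away (X, 71259253 to 71269260) differed in the opposite direction. It measured 40.7 ± 1.7 CPM in frontal cortex wild type and 87.0 ± 2.0 CPM in the frontal cortex knockout (SD, n = 2 each), a log2 fold change of 1.10 with an adjusted p of 0.0830 in edgeR, and of 0.00099 with the frontal cortex libraries fitted alone. In hippocampus it measured 45.4 and 74.2 CPM in the libraries labelled wild type 1 and 2, and 79.9 and 41.4 CPM in those labelled knockout 1 and 2. A further locus 86087 bp away (X, 71417063 to 71417263) also parted the hippocampal libraries in this way, with 7.49 and 2.94 CPM in those labelled wild type 1 and 2 and 3.07 and 8.29 CPM in those labelled knockout 1 and 2, but its frontal cortex log2 fold change was -0.01 (edgeR adjusted p = 0.993). The similarity of whole libraries followed the same order. The chi-square per degree of freedom between libraries, which is 1 for counting error alone, was 18.5 between the hippocampal libraries labelled wild type and 34.4 between those labelled knockout. It was 9.18 between wild type 1 and knockout 2 as labelled, and 7.35 between wild type 2 and knockout 1 as labelled. In frontal cortex it was 16.01 and 16.36 within the genotypes and 29.1 to 45.6 between them. Directions drawn below from the hippocampal genotype labels carry this limit.

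**Figure D1:**
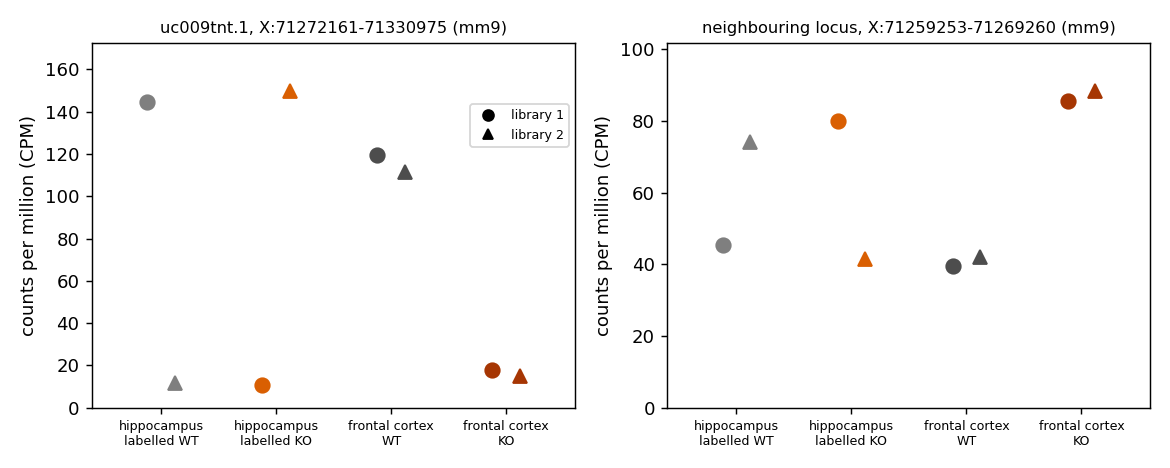
CPM (linear axis from 0) of the X-linked locus uc009tnt.1 (left) and of its neighbour (right). Among X-linked loci with a mean of at least 1 CPM, uc009tnt.1 fell most in the frontal cortex knockout. There is 1 point per library, and the marker shape gives the library number. Frontal cortex wild type (119 and 111 CPM) lies above the knockout (18.1 and 15.2 CPM) on the left, whereas each labelled hippocampal group holds 1 high and 1 low library.

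The frontal cortex comparison asked which transcripts differ in a brain region that lacks MeCP2. In the knockout, 203 loci rose and 172 fell out of 18120 tested (edgeR quasi-likelihood test, adjusted p under 0.05), with a median absolute log2 fold change of 0.58. Changes above 2-fold were seen for 39 rising and 27 falling loci. The largest fall by the naming rule was that of uc008jfl.1 (chromosome 2, 32240157 to 32243259), from 6.50 ± 0.52 CPM in wild type to 0.233 ± 0.036 CPM in the knockout (SD, n = 2 each; log2 fold change -4.79, SE 0.45, edgeR adjusted p = 0.0039). The locus uc007xwq.1 (chromosome 15, 102488126 to 102490833) fell from 3.20 ± 0.30 to 0.840 ± 0.113 CPM (SD, n = 2 each; log2 fold change -1.93, SE 0.27, edgeR adjusted p = 0.0205). The locus uc009ubw.1 (X, 104032421 to 104035982) had 0 counts in both wild-type libraries and 14 counts over the knockout libraries, at least 4.24-fold higher when wild type is set to a floor of 3 counts over the group (edgeR adjusted p = 0.0486). The locus uc008eea.2 (chromosome 18, 20119431 to 20160598) rose from 4 counts over the wild-type libraries to 36 counts over the knockout libraries (log2 fold change 2.96, SE 0.50, edgeR adjusted p = 0.0318). Both rising examples were low in frontal cortex and stood at 2.95 to 4.49 CPM in the hippocampal libraries. They met the required mean over all 8 libraries only through hippocampus, so a higher hippocampal level was built into their choice. The call of uc009ubw.1 was lost in limma-voom (adjusted p = 0.0697), with every distinct span (adjusted p = 0.0504) and without either library labelled hippocampus wild type (adjusted p = 0.0696 each), and that of uc008eea.2 was lost in limma-voom (adjusted p = 0.105). The calls of all 4 named loci were lost when any 1 frontal cortex library was left out.

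The number of frontal cortex calls depended on the libraries and terms in the fit. With the replicate numbers as a block, 0 loci were called. The labels do not say that these numbers pair the libraries. Across the genotypes, however, frontal cortex libraries of equal number were more alike (chi-square per degree of freedom 29.1 and 30.9) than those of unequal number (45.6 and 42.4). The 4 frontal cortex libraries fitted alone gave 1243 calls, which included 369 of the 375 loci, all in the same direction. The spread, as the biological coefficient of variation, was 7.93% in that fit and 10.2% with all 8 libraries. Pooling raises the spread at loci that differ within a labelled hippocampal group. At the X-linked locus the edgeR adjusted p was 0.226, and 0.000103 with frontal cortex alone. How much of the difference in calls came from pooling was not tested. DESeq2, which also used all 8 libraries, gave 1213 calls, and a test of every distinct span gave 600. Leaving out 1 frontal cortex library left 3 and 6 calls (without wild type 1 and 2) or 12 and 9 calls (without knockout 1 and 2), and leaving out 1 hippocampal library gave 188 and 183 calls (without the libraries labelled wild type 1 and 2) or 901 and 912 (without those labelled knockout 1 and 2).

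Loci with long genomic spans lay higher in the frontal cortex knockout. The 2358 tested loci of over 100 kb had a median log2 fold change of 0.10, against -0.02 for the 15762 others, a difference of 0.12. The median went from -0.11 for spans of 2 to 5 kb through 0.01 for spans of 20 to 50 kb to 0.11 for spans over 200 kb. Among called loci of over 100 kb, 68 rose and 17 fell, whereas among shorter called loci 135 rose and 155 fell (Fisher's exact test, two-sided, p = 3.09e-08). Rising loci had a median span of 59.1 kb and falling loci one of 9.85 kb, with 20.7 kb over all tested loci. The set test with a preset correlation of 0.01 (camera) gave p = 1.74e-07 for the long loci. That call was lost with an estimated correlation of 0.097 (camera p = 0.162), and Fisher's exact test makes no allowance for such a correlation. Each library was also set against the mean of its region: long loci lay above the others by 0.08 and 0.02 in the frontal cortex knockout libraries and by -0.03 and -0.08 in the wild-type libraries. Libraries of the same group differed in this measure by up to 0.08, the value between the hippocampal libraries labelled wild type, and by 0.06 within each frontal cortex group.

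**Figure D2:**
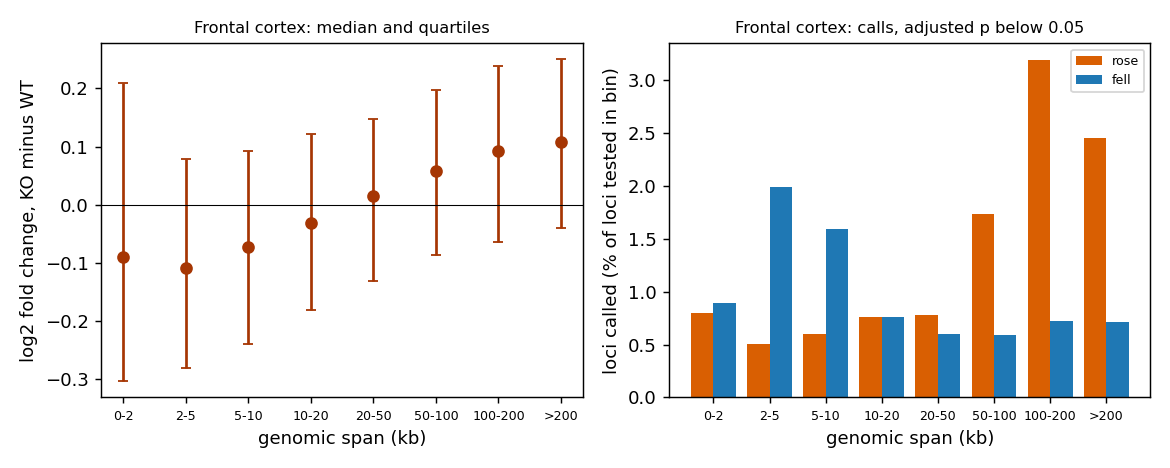
Frontal cortex knockout minus wild type by genomic span of the locus in kb. Points are medians of the log2 fold change over the loci of a bin with bars from the lower to the upper quartile (left), and bars give the percentage of tested loci in each bin that rose or fell at an adjusted p under 0.05 (right); medians go from -0.11 at 2 to 5 kb to 0.11 above 200 kb.

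Loci that rose in the frontal cortex knockout were more often loci that hippocampus expressed at a higher level. The region preference was taken from the contrast of hippocampus with frontal cortex averaged over both genotypes, whose group means and spread follow the labels. Of the 203 rising loci, 104 (51.2%) were significantly higher in hippocampus, against 23.2% of all tested loci. Of the 172 falling loci, 70 (40.7%) were significantly higher in frontal cortex, against 23.3% of all tested loci. In hippocampus, 51 (29.7%) of them were higher. Genotype and region calls came from the same fit, and called loci differed by region more often in either direction. Only 45 of the 203 rising and 51 of the 172 falling loci lacked a region call, against 9699 of all 18120. Loci measured precisely enough for 1 call may also get the other, which may raise both shares against all tested loci. Rising and falling loci differed in their share of hippocampus-higher loci (Fisher's exact test, two-sided, odds ratio 2.49, p = 2.50e-05) and of frontal cortex-higher loci (odds ratio 0.53, p = 0.00424). A further 54 rising loci (26.6%) were significantly higher in frontal cortex. With region as the only term, so that no genotype label entered, 79 rising loci (38.9%) and 41 falling loci (23.8%) were higher in hippocampus (odds ratio 2.03, Fisher's exact test p = 0.0019), against 21.8% of all tested loci. The difference in frontal cortex-higher loci between rising (20.2%) and falling loci (26.7%) was then lost (Fisher's exact test p = 0.142).

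**Figure D3:**
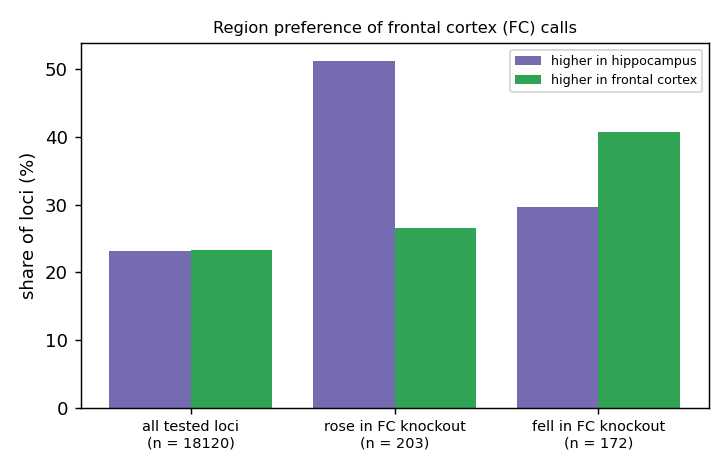
Percentage of loci that were significantly higher in hippocampus or in frontal cortex, averaged over both genotypes, among all 18120 tested loci and among those that rose (203) or fell (172) in the frontal cortex knockout. Hippocampus-higher loci make up 51.2% of the rising loci, 29.7% of the falling loci and 23.2% of all tested loci.

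The same question was asked of the hippocampus. As labelled, no locus passed the threshold in hippocampus: edgeR, DESeq2 and limma-voom each called 0 of 18120 loci. Only 60 loci had an unadjusted p under 0.05 in edgeR, where 906 would be given by chance. The smallest p belonged to uc009gec.1 (chromosome 7, 31099835 to 31104064), with 2.94 ± 0.03 CPM in the libraries labelled knockout and 1.96 ± 0.10 CPM in those labelled wild type (SD, n = 2 each; log2 fold change 0.58, SE 0.15, edgeR adjusted p = 1). The 2358 long loci differed from the 15762 others by 0.0015 on the log2 scale, which camera did not call. The sign of this difference changed when the library labelled wild type 1 (-0.0425) or that labelled knockout 1 (-0.0107) was left out. Camera called the set, in opposite directions, without the library labelled wild type 1 (-0.0425) and without that labelled wild type 2 (0.0409). The spread within labelled groups, as the biological coefficient of variation, was 12.4% in hippocampus and 7.93% in frontal cortex, each region fitted alone. These values describe the groups as labelled, which the X-linked locus goes against.

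None of the 375 frontal cortex loci was called in hippocampus as labelled. At an unadjusted p under 0.01, 3 loci were higher in the hippocampal libraries labelled knockout, 812 were higher and 772 lower in the frontal cortex knockout, and 0 were shared, where 0.134 would be by independent lists, so too few hippocampal loci passed to test for sharing. Across the 18120 loci, which are not independent replicates, the log2 fold changes of the regions had a Spearman's rho of -0.00053. Each labelled hippocampal group mixed a high and a low library at the X-linked locus. If genotypes were exchanged between these libraries, a genotype effect would largely cancel in the labelled contrast. This rho therefore cannot show whether the regions change the same loci.

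The effect common to both regions was tested with 4 libraries labelled knockout against 4 labelled wild type, with region as a term. No locus was called by edgeR, DESeq2 or limma-voom, and 1028 loci had an unadjusted p under 0.05 in edgeR, where 906 would be given by chance. The X-linked locus had a log2 fold change of -1.34 (SE 0.93, edgeR adjusted p = 0.744), which ranged from -2.82 (without the library labelled hippocampus knockout 2) to -0.87 (without frontal cortex knockout 2) when 1 library was left out. Long loci lay 0.06 above the others (camera p = 5.26e-07), a call that was lost with an estimated correlation (p = 0.180). The difference was 0.0351 without frontal cortex wild type 2 and 0.0360 without frontal cortex knockout 1. The hippocampal labels enter these values.

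At 5 loci the genotype effect differed between the regions (edgeR interaction test, adjusted p under 0.05), and at each of them the frontal cortex knockout was higher than wild type while the hippocampal groups as labelled were close to each other. The neighbouring loci uc007ijm.1 and uc007ijk.1 (chromosome 11, 32196489 to 32197310 and 32183672 to 32184493) have equal spans of 0.822 kb. They rose from 56.0 ± 1.8 to 182 ± 17 CPM and from 57.2 ± 4.0 to 189 ± 18 CPM in frontal cortex (SD, n = 2 each). Their log2 fold changes there were 1.70 (SE 0.11) and 1.72 (SE 0.11), with an edgeR adjusted p of 0.00093 for each. Over the 4 hippocampal libraries, whatever their labels, they ranged from 53.4 to 64.4 CPM and from 54.5 to 65.1 CPM. The other 3 loci lie on chromosome 17 (459.8 kb), chromosome 7 (1.41 kb) and chromosome 10 (17.8 kb), and their frontal cortex log2 fold changes were 1.26, 1.32 and 2.11. Their highest hippocampal library exceeded the lowest by 1.18, 1.22 and 1.30 times. How reads of similar copies were counted is not given in the sources used here, so the values of the paired chromosome 11 loci are uncertain. The planned lists of blood and striatal genes could not be run without names. Other tissue in the frontal cortex knockout pools was therefore not tested as a source of these 5 differences. DESeq2 called 156 loci, and 0 loci were called without frontal cortex wild type 1, wild type 2 or knockout 2.

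**Figure D4:**
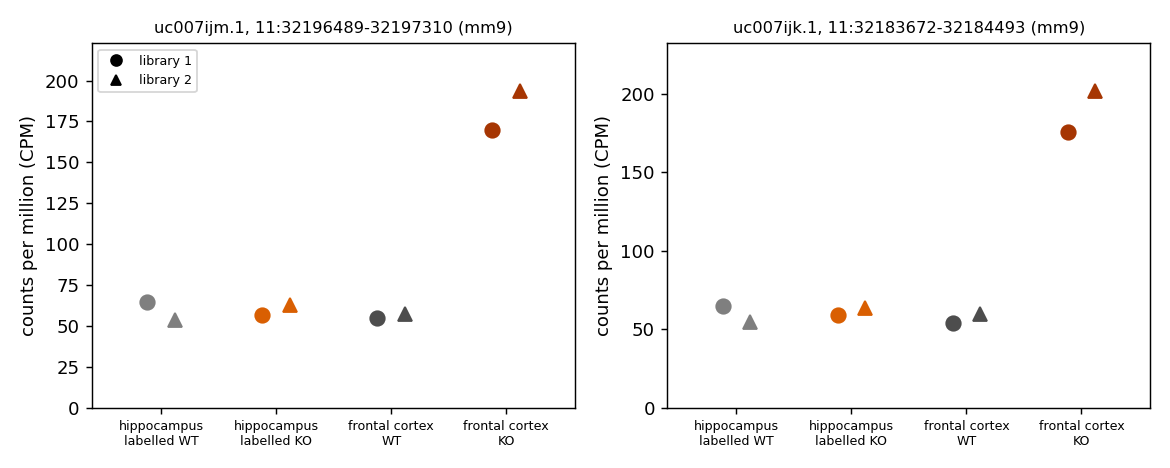
CPM (linear axis from 0) of uc007ijm.1 and uc007ijk.1, the loci with the smallest p for a difference of the genotype effect between regions, with 1 point per library and the marker shape giving the library number. The frontal cortex knockout libraries average 182 and 189 CPM, above the other 6 libraries, all at or below 65.1 CPM.

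The regions themselves were compared in wild type. Without gene names, this comparison cannot check the region labels, since exchanged labels would give the same calls with the signs reversed. Hippocampus and frontal cortex differed at 6284 of 18120 loci (34.7%), with 3090 higher in the hippocampal libraries labelled wild type and 3194 higher in frontal cortex (edgeR, adjusted p under 0.05). By fitted values, 112 loci were over 16-fold higher in hippocampus and 60 in frontal cortex. The locus uc009dkr.1 (chromosome 6, 116642743 to 116666776) had 758 counts over the hippocampal libraries labelled wild type and 0 in frontal cortex wild type, at least 211-fold higher for the pooled pairs against a floor of 3 counts over the group. The libraries labelled wild type 1 and 2 held 7.92 and 3.20 CPM of it, those labelled knockout 1 and 2 held 3.16 and 8.48 CPM, and its fitted log2 fold change of 11.41 was 10.57 without the library labelled hippocampus wild type 1. The locus uc009ubw.1 (X, 104032421 to 104035982) had 435 counts against 0, at least 121-fold higher on the same floor. On the frontal cortex side, uc009uhh.1 (X, 132114326 to 132133316) had 440 counts in frontal cortex wild type and 2 in the hippocampal libraries labelled wild type, a ratio of 264 with a 95% exact interval from 72.6 to 2184 that covers counting error only. Both of these hippocampal counts came from the library labelled wild type 1, and the fitted log2 fold change of uc009uhh.1, -7.87, was -10.91 without that library and -7.09 without the library labelled wild type 2. The locus uc009bpe.1 (chromosome 6, 41483863 to 41498351) stood at 44.4 ± 1.3 CPM in frontal cortex and 0.473 ± 0.037 CPM in hippocampus (SD, n = 2 each; log2 fold change -6.54, SE 0.28, edgeR adjusted p = 8.8e-07). It represents 62 merged transcript spans and overlaps a locus on the other strand, so its value is uncertain.

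Long loci were more often higher in hippocampus. Among called loci of over 100 kb, 730 were higher in hippocampus and 491 in frontal cortex, whereas among shorter called loci 2360 were higher in hippocampus and 2703 in frontal cortex (Fisher's exact test, two-sided, odds ratio 1.70, p = 1.56e-16). Averaged over both genotypes, 8421 loci differed between the regions, and 8060 with region as the only term, so that no genotype label entered. A test of every distinct span gave 12635 calls, and the count was 3777 without frontal cortex wild type 2.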

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

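The tests of depth, of hippocampal tissue and of the variation of long loci within groups were chosen only after the result was seen; the other tests of this part were fixed before theirs was measured.

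The genotype effect differed between the regions at 5 loci by the interaction test in edgeR. Whether this came from the genotype or from other tissue in the frontal cortex knockout pools was not tested. As hippocampal effect (as labelled) minus frontal cortex effect on the log2 scale, the differences were -1.68 for uc007ijm.1 and -1.69 for uc007ijk.1 (adjusted p = 0.0171 each), and -1.20, -1.32 and -2.37 for the loci on chromosomes 17, 7 and 10 (adjusted p = 0.0319 each). For the effect over both regions, the labels called 0 loci, so that each of the 34 splits of the 8 libraries into 4 and 4 that could be fitted, the labelled one included, reached that count by necessity, and the count of splits decides nothing about chance. The highest other split called 1905 loci and put the libraries labelled hippocampus wild type 1 and knockout 2 with the frontal cortex wild types. The split that put the same hippocampal pair with the frontal cortex knockouts called 15 loci. This contrast points to a direction of change that the hippocampal pairs share with the frontal cortex genotypes.

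The hippocampal libraries labelled wild type 1 and knockout 2 stood apart from those labelled wild type 2 and knockout 1, and a difference in depth is argued against: the X-linked locus differed by at least 12.5-fold in CPM between these pairs, while the library sizes differed by at most 1.22 times. A score of the frontal cortex calls (mean log2 CPM of the 203 rising minus the 172 falling loci, without loci within 1 Mb of the X-linked locus) was 0.073 and 0.060 in the libraries labelled wild type 2 and knockout 1, and -0.063 and -0.070 in those labelled wild type 1 and knockout 2, a gap of 0.124 in the direction of the frontal cortex knockout (0.157 and 0.159 against -0.151 and -0.164 by the calls of frontal cortex fitted alone, and -0.63 and -0.64 in wild type against 0.64 and 0.63 in the knockout of frontal cortex, where the scored loci were picked). Of the 3 ways to split the 4 hippocampal libraries into pairs, 1 called 1519 loci and the labelled split called 0. A candidate explanation is that the libraries labelled hippocampus wild type 2 and knockout 2 carry each other's genotype, with the X-linked locus as the targeted gene, but its name was not looked up. At the X-linked locus the high hippocampal pair (144 and 149.8 CPM) stood near frontal cortex wild type (119 and 111 CPM). The low pair (11.6 and 10.7 CPM) stood near the frontal cortex knockout (18.1 and 15.2 CPM). Its neighbour 2900 bp away was matched to the frontal cortex genotypes in the same way (45.4 and 41.4 against 74.2 and 79.9 CPM). Another difference between the pairs, such as dissection, stays open beside an exchange. A locus 86087 bp away goes with such a difference. It parted the hippocampal pairs (7.49 and 8.29 against 2.94 and 3.07 CPM) without a frontal cortex difference (log2 fold change -0.01).

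Loci that rose in the frontal cortex knockout were often loci with a higher level in hippocampus. More hippocampal tissue in the knockout pools is argued against for the 26.6% of rising loci that were significantly lower in hippocampus than in frontal cortex (20.2% with region as the only term). Whether such tissue was present could not be decided. The 41 loci that were over 16-fold higher in hippocampus averaged over both genotypes, with a mean of at least 1 CPM, were used. They had a median log2 fold change of 0.675 (bootstrap interval 0.063 to 0.942), and 29 of them lay above 0. The median was above the bound of 0.1 set for such tissue although the interval reached below it. The median share of hippocampal RNA implied by these loci was 1.32% (quartiles -0.15% and 2.38%). That share would give the 104 rising loci that hippocampus expressed higher a median log2 rise of 0.027, against 0.591 seen. It would account for 50% of the rise or more at only 4 of the 104 loci. These values argue against hippocampal tissue in this share as the main source of the rise at the rest of the 104. An effect of the knockout on such loci stays open, as does tissue from other sources.

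Loci with long spans lay higher in the frontal cortex knockout. Lower expression of long loci as the cause is argued against. Of the 2358 long loci, 1162 lay in the highest of 3 equal parts of the expression range and 452 in the lowest. They also exceeded the others in each part, by 0.0485 in the lowest, 0.148 in the middle and 0.110 in the highest. Variation between libraries of the same group cannot be told apart from a genotype effect with 2 libraries per group: the largest such difference was 0.0802, between the hippocampal libraries labelled wild type, against 0.117 between the frontal cortex genotypes and 0.0565 at most within them. That hippocampal pair is one whose labels the X-linked locus goes against (long loci lay at -0.042 and -0.011 in the libraries labelled wild type 1 and knockout 2, and at 0.041 and 0.015 in those labelled wild type 2 and knockout 1), and by the frontal cortex groups alone the genotype difference would exceed 1.5 times that within groups. A length-dependent effect of the knockout is one hypothesis, and a shift from library preparation, such as RNA quality or intron content, is another that was not tested.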

How the results depend on the processing

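Every distinct span, the set without loci that overlap the other strand, the regions averaged over both genotypes or with region as the only term and the long loci of frontal cortex fitted alone were chosen after the data were seen. The frontal cortex count of 375 became 1384 at an adjusted p under 0.1, 1243 with the region fitted alone, 1213 with DESeq2, 600 with every distinct span and 3 to 912 when 1 library was left out. The hippocampal count of 0 ranged from 0 to 1 when 1 library was left out, and that over both regions stayed at 0 in every alternative run. The 5 loci of the difference between regions became 18 at an adjusted p under 0.1, 21 with no filter, 10 with robust empirical Bayes, 9 without loci that overlap the other strand, 156 with DESeq2 and 0 to 12 when 1 library was left out. The 6284 loci of the region comparison became 12635 with every distinct span, where more features were tested, and 3777 to 6923 when 1 library was left out. For long loci, the difference in frontal cortex was 0.117 (p = 0.162) with an estimated correlation and 0.118 (p = 0.197) when the region was also fitted alone, and over both regions 0.0596 (p = 0.180, and 0.0351 to 0.0892 when 1 library was left out); fewer effective loci follow from the higher correlation. In hippocampus the difference for long loci ranged from -0.0425 to 0.0409 when 1 library was left out. Except where stated, the cause of these changes was not tested.

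The replicate numbers were used as a replicate block, although the labels do not say that they pair the libraries. Deviations of same-numbered libraries correlated at -0.51 in hippocampus and 0.49 in frontal cortex, and at -0.10 and -0.34 across the regions in wild type and knockout as labelled. The values with hippocampus take its labels as given, which the X-linked locus goes against. In frontal cortex, splitting the libraries by number gave 1052 loci with an unadjusted edgeR p under 0.05. Setting wild type 1 and knockout 2 against the others gave 16. Frontal cortex libraries of equal number thus shared differences. With this block, 0 loci were called in frontal cortex, 0 in hippocampus, 0 over both regions, 8 for the difference between regions and 4550 for the regions, and the X-linked locus in hippocampus had a log2 fold change of -0.0301. That locus had 0.04 in the designed fit and -0.0815 with limma-voom, and -2.87 to 2.80 when 1 library was left out; its difference between regions was 2.83 and -0.0729 to 5.59 when 1 library was left out. The planned gene lists were not run, since no names were available by the routes used here. The overlap of the regions' calls was 0 in each alternative, which held 0 to 3 hippocampal loci, so it says nothing on sharing. The depth of 54500111 to 70221480 counts per library leaves loci near 0 counts, such as uc009ubw.1, at the floor.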

Other observations

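The tests of chromosomes and of neighbouring calls were chosen after the data were seen. No chromosome held more or fewer frontal cortex calls than the rest of the genome (21 two-sided Fisher's exact tests, smallest unadjusted p = 0.166 for chromosome 14, all adjusted p = 1). On chromosome X, 6 loci rose and 7 fell out of 634 tested. Called loci lay next to each other more often than in a random order: 30 pairs of neighbouring tested loci were both called, against a mean of 7.78 and a highest value of 16 in 1000 random orders. Of these pairs, 27 moved in the same direction, and 15 overlapped each other on opposite strands, where the counts share reads. The random orders did not keep this sharing, so whether neighbouring calls are in excess without it was not tested.

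The segment around the X-linked locus was tested for an excess of calls, as a strain segment around a targeted gene would give. None of the 88 tested loci within 5 Mb was called, against 375 of 18032 others (1-sided Fisher p = 1), whereas with the region fitted alone 8 of the 88 and 1235 of the others were called (p = 0.256). Those 8 include the X-linked locus itself and its neighbour 2900 bp away, so they are not all calls of a surrounding segment. The number of loci is too small to decide whether a segment that differs between the genotypes is present.

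Every library held counts on chromosome Y, from 9903 to 15304, and none held counts on the mitochondrial chromosome. Long loci took between 20.6% and 22.3% of the counts of a library.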
